A study of Drosophila melanogaster with 18 samples.

How the data were processed

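RNA from whole adult Drosophila melanogaster of 3 genotypes was sequenced on 2 platforms, with 3 libraries per genotype per platform and 18 libraries in all. The driver control carried GR23E10-gal4 alone, dec2WT flies carried the driver with UAS-dec2WT, and dec2P384R flies carried it with UAS-dec2P384R. Gal4 is a yeast transcription factor that switches on any transgene placed behind its UAS binding sites. Per the labels, flies were kept at 25 °C under 12 h of light and 12 h of darkness, collected at zeitgeber time 3 (hours after lights on), chosen for a difference in daytime sleep, and extracted in lots of about 70 animals. The labels call the 3 libraries of a genotype independent biological replicates. They give no sex, age, collection batch or sequencing batch, and they leave open whether both platforms used the same RNA. One Illumina column spells the mutant with its digits exchanged; its remaining name matches dec2P384R replicate 2 alone, and it was used as that library.

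The submitters' processing notes name HISAT2, featureCounts 1.5.0-p3, minimap2, Salmon and DESeq2, without roles or order. The genome build and the strand setting of the counting were not given in the sources used here. Of the 17626 gene identifiers shared with Ensembl release BDGP6.54, 99.3% had identical coordinates. Positions are printed as deposited with the Illumina values, and gene symbols are the deposited ones. Without strand, reads of overlapping genes on opposite strands cannot be told apart. The transgenes are not among the measured genes, so their expression was not analysed here.

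The Illumina table, deposited under a name that speaks of counts, held FPKM values (fragments scaled to gene length and library size) for 17972 genes, of which 219 were gene models without an identifier in the reference annotation. Multiplying each deposited FPKM value by gene length and by a constant of its library gave whole reads for 100% of values, within 1e-08. The constant was taken from the counts that the authors deposited for the genes in their Illumina comparison tables. Those constants were proportional to the median-of-ratios factors of the recovered reads, so the authors' FPKM values already carry that scaling. The recovered reads summed to between 18057117 and 28293197 per library. The Nanopore table as deposited by the authors held estimated counts, of which 55.1% were not whole; they summed to between 1922380 and 4659601 per library over 13969 genes. The authors also deposited tables of their own comparisons with log2 fold changes and adjusted p-values for each platform. Their Illumina tables list calls of at least 2-fold alone. Another 36 columns of values per library in the authors' tables were not used.

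Illumina libraries were polyA-enriched with paired reads of 150 nt, and Nanopore libraries were direct cDNA. Illumina FPKM values were tested with limma 3.58.1 (trended empirical Bayes) on log2(FPKM + 0.5), over the 13418 genes with at least 0.5 FPKM in at least 3 of 9 libraries. Fold changes are therefore on the log2(FPKM + 0.5) scale and understate changes of low genes. The test fixed before the data were examined was edgeR's quasi-likelihood test, which needs counts; with FPKM deposited, it became an added alternative on the recovered reads. Nanopore estimated counts were rounded and tested with edgeR 4.0.16 (TMM scaling, filterByExpr, quasi-likelihood F-test) over 11393 genes. Standard errors of Nanopore folds were derived from the F statistic. All 9 libraries of a platform entered 1 model with genotype as the factor, so that the genotypes shared their estimate of the spread. Tests were two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. R was version 4.3.3. A fold against a group with no reads was set against a floor of 3 counts per library and is given as a lower bound, which covers counting error only.

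Gene lists were fixed before the data were examined: 41 lists of energy metabolism, digestion, protein homeostasis, stress response, immunity, signalling, sleep and clock genes, and of markers of tissues and of each sex. They were tested with camera at a preset correlation between genes of 0.01, adjusted over the lists with at least 3 measured members, and again with an estimated correlation. Members past the threshold were also counted with the adjusted p taken over the list alone. Genes named in the text followed a rule of the same date. For each Illumina comparison these were the 10 largest rises and the 10 largest falls with adjusted p under 0.05, a mean of at least 2 CPM, no overlap between the libraries of the groups, and a symbol other than a CG, CR, antisense or long noncoding name. They also included up to 4 members of each list past its test, 8 clock genes, h and w. Chance parts 3 libraries from 3 without overlap for 10% of genes.

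Replicate numbers were checked for pairing by correlating the libraries' deviations from their group means across genes. For dec2P384R and the driver control on Illumina, the libraries of each number correlated above 0.1 (0.26, 0.12 and 0.25), so the numbers were taken to pair these libraries from the data, not from the labels. The Nanopore libraries of these 2 genotypes correlated at −0.12, 0.084 and −0.058, so the pairing is uncertain. The main fit has no block, and a fit with replicate number as a block is given beside a result of that comparison where it changes a call. On Illumina, dec2P384R with dec2WT gave 0.24, 0.04 and 0.21, and dec2WT with the driver control gave 0.076, −0.029 and 0.18. Of the 9 Illumina libraries, 7 correlated best with a library of their own number among the other genotypes. No replicate libraries were duplicates: chi-square per degree of freedom between libraries of a genotype ran from 5.85 to 60.7 on Illumina and from 4.65 to 15.1 on Nanopore.

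The procedures were tested on simulated counts with 200 changed genes drawn from the genes at or above the median expression. For dec2P384R against the driver control, the Illumina procedure recovered 29.9% of genes changed 1.5-fold, 98.5% of those changed 2-fold and 100% of those changed 4-fold. The Nanopore procedure recovered 14.9%, 74.6% and 100%. A 1.5-fold change that was not called is therefore not shown to be absent. Alternatives were DESeq2 1.42.0, edgeR on recovered reads, no filter on low values, pseudocounts of 0.1 and 1, TMM rescaling, unrounded counts, a fit with the 6 compared libraries alone, a replicate block, and the omission of each library in turn.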

Results

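The data were 9 Illumina and 9 Nanopore transcriptomes of whole flies, 3 libraries for each of 3 genotypes on each platform. Dec2 is a basic helix-loop-helix repressor of transcription, its P384R form is known from people with naturally short sleep, and the GR23E10 driver is known for labelling sleep-promoting neurons of the dorsal fan-shaped body. Illumina libraries held 21382861, 28293197 and 22586691 reads on genes in the driver control, 24709551, 19231073 and 21343776 in dec2WT, and 21738341, 19327174 and 18057117 in dec2P384R (replicates 1 to 3). Nanopore libraries held 4156725, 3602232 and 3777162 estimated counts in the control, 4659601, 3332335 and 3486376 in dec2WT, and 1922380, 3566122 and 2391381 in dec2P384R. On Illumina the mitochondrial rRNA mt:lrRNA took 4.37% to 5.31% of reads in 8 libraries and 6.45% in dec2P384R replicate 2.

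The first comparison, dec2P384R against the driver control, asked how the transcriptome differed in flies with the mutant transgene. MtnC (FBgn0038790, chromosome 3R, 20360308 to 20360634), a metallothionein that binds heavy metal ions, rose 67.5-fold on Illumina, from 2.99 ± 0.88 to 241 ± 94 FPKM (SD, n = 3 per group), while its Nanopore log2 fold change was −0.16 ± 0.26 (SE). The odorant-binding protein gene Obp99b rose 14.7-fold (log2 3.88 ± 0.52 SE), from 30 ± 18 to 369 ± 36 FPKM. Storage protein genes of the fat body rose with it: Lsp1alpha 15.2-fold (3.92 ± 0.64) and Lsp1beta 7.71-fold (2.95 ± 0.57). mthl8, of the methuselah-like receptor family, had no reads in the 3 control libraries and was at least 109-fold higher in dec2P384R on Illumina and at least 10.3-fold higher on Nanopore. The trypsin genes gammaTry and deltaTry fell 6.24-fold (−2.64 ± 0.20) and 3.89-fold (−1.96 ± 0.15), and the lysozyme gene LysP fell 3.67-fold (−1.88 ± 0.24).

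Further rises named by the rule were Lsp2 (6.12-fold), the trypsin gene Try29F (4.32-fold), the immune peptide gene IM1 (4.26-fold), the Rab GTPase gene RabX2 (3.29-fold) and the cecropin gene CecA2 (3.13-fold). Further falls were the serine protease genes Jon99Fi (3.64-fold) and Jon65Ai (2.39-fold), vanin-like (3.56-fold), the UDP-glycosyltransferase gene Ugt86Dd (3.21-fold), the cytochrome P450 genes Cyp6a14 (2.87-fold) and Cyp6w1 (2.53-fold), and the chromatin assembly gene Acf (2.42-fold). Limma adjusted p (Benjamini-Hochberg) was 5.4e-06 for MtnC, 3.39e-06 for mthl8, 0.00264 for Obp99b, 4.44e-05 for gammaTry and at most 0.0304 (Lsp2) for the others. In all, 376 of 13418 genes passed, 219 higher and 157 lower in dec2P384R. The count was 179 without driver control replicate 2 and 192 without driver control replicate 3, and the balance turned without dec2P384R replicate 2 (137 higher, 172 lower); without driver control replicate 1 it was 189 higher and 90 lower. Calls were lost for Lsp2 in 5 of the 9 omissions of a library (limma adjusted p up to 0.104, without dec2P384R replicate 3) and without a filter on low values (0.0586). They were also lost for Lsp1beta without dec2P384R replicate 2 (0.0589) or 3 (0.0743), and for Jon65Ai without driver control replicate 2 (0.058) or 3 (0.0523). Values of gammaTry, deltaTry, LysP and CecA2 are uncertain because near-identical neighbours can share their reads, and Try29F overlaps CG18661 on its own strand.

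Among gene groups, digestive serine proteases were shifted down in dec2P384R: 5 of 31 fell, 1 (Try29F) rose and 25 did not pass, with a median log2 fold change of −0.44 (camera adjusted p = 6.72e-06). Adjusted over the list alone, 13 of these proteases fell and 3 rose. Antimicrobial peptide genes were shifted up: IM1, CecA2, CecA1 and CG15067 rose, none of the 33 fell and 29 did not pass, with a median of 0.58 (camera adjusted p = 0.000403); adjusted over the list alone, 4 rose and 1 fell. On Nanopore the antimicrobial peptides were shifted the other way, with a median of −0.33 over 30 genes, 0 past over all genes, 2 lower adjusted over the list alone, and a camera adjusted p of 0.0158 (0.983 with an estimated correlation). Of 35 glutathione S-transferase genes, GstD1 (1.45-fold), GstD7 (1.65-fold) and GstD3 (1.72-fold) rose and 32 did not pass; adjusted over the list alone, 5 rose and 1 fell (camera adjusted p = 0.035). Of 27 phototransduction genes, the channel gene trpl fell 1.54-fold and 26 did not pass; adjusted over the list alone 3 fell (camera adjusted p = 0.035). With an estimated correlation, adjusted p = 0.914 for each of these lists.

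Smaller shifts came without any member past the threshold over all genes in the main limma fit. The 25 genes of the tricarboxylic acid cycle had a median of −0.13 (camera adjusted p = 0.00437), and adjusted over the list alone 1 was lower. For 15 glycolysis genes the median was −0.21 (camera adjusted p = 0.0105), and for 72 mitochondrial ribosomal protein genes −0.09 (camera adjusted p = 0.035); 0 members of either passed adjusted over the list alone. On Nanopore the mitochondrial ribosomal list was shifted the other way (73 genes, median 0.09, camera adjusted p = 0.0195, 0 past over all genes or adjusted over the list alone, and adjusted p = 0.983 with an estimated correlation). The tricarboxylic acid cycle and glycolysis lists did not pass on Nanopore. The 20 starch and sugar digesting enzymes had a median of 0.44 (camera adjusted p = 0.00849), and 38 testis genes one of 0.10 (camera adjusted p = 0.035), again with 0 past adjusted over the list alone. For the 4 Turandot stress peptide genes the median was 0.78 (camera adjusted p = 0.035, and 0.052 with replicate number as a block), with 2 higher adjusted over the list alone. With an estimated correlation, adjusted p = 0.914 for each of these 6 lists as well, and the remaining 31 lists did not pass. The replicate block also brought kdn (citrate synthase, −0.42 ± 0.10), Mal-B2 (0.47 ± 0.14), mRpL23 (−0.45 ± 0.15) and ninaG (−0.57 ± 0.14; folds as without the block) past the threshold, with limma adjusted p of 0.0491, 0.0178, 0.0372 and 0.0385.

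Among the 10 lists past, only the proteases and antimicrobial peptides passed whichever library was left out, with camera adjusted p of at most 0.00475 (without dec2P384R replicate 1) and 0.0165 (without dec2P384R replicate 2). Without driver control replicate 2, or without dec2P384R replicate 1, 4 lists passed. The mitochondrial ribosomal list changed direction without dec2P384R replicate 3 (camera adjusted p = 0.974), and so did the testis list without driver control replicate 2 (0.967). Calls of single members were also fragile: GstD1, GstD7 and CecA1 each lost theirs in 7 of the 9 omissions, GstD3 and CG15067 in 6, and trpl in 4 (limma adjusted p up to 0.158, CG15067 without driver control replicate 2). With all libraries kept, GstD7 also lost its call under DESeq2 (adjusted p = 0.139) and edgeR (0.0961) on recovered reads, and GstD1, GstD3 and GstD7 did so in limma with the 6 compared libraries alone or without a filter on low values. In limma, CecA1 (adjusted p = 0.0952) and trpl (0.07) lost theirs with the 6 compared libraries alone, and CG15067 without a filter (0.0712).

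**Figure D1:**
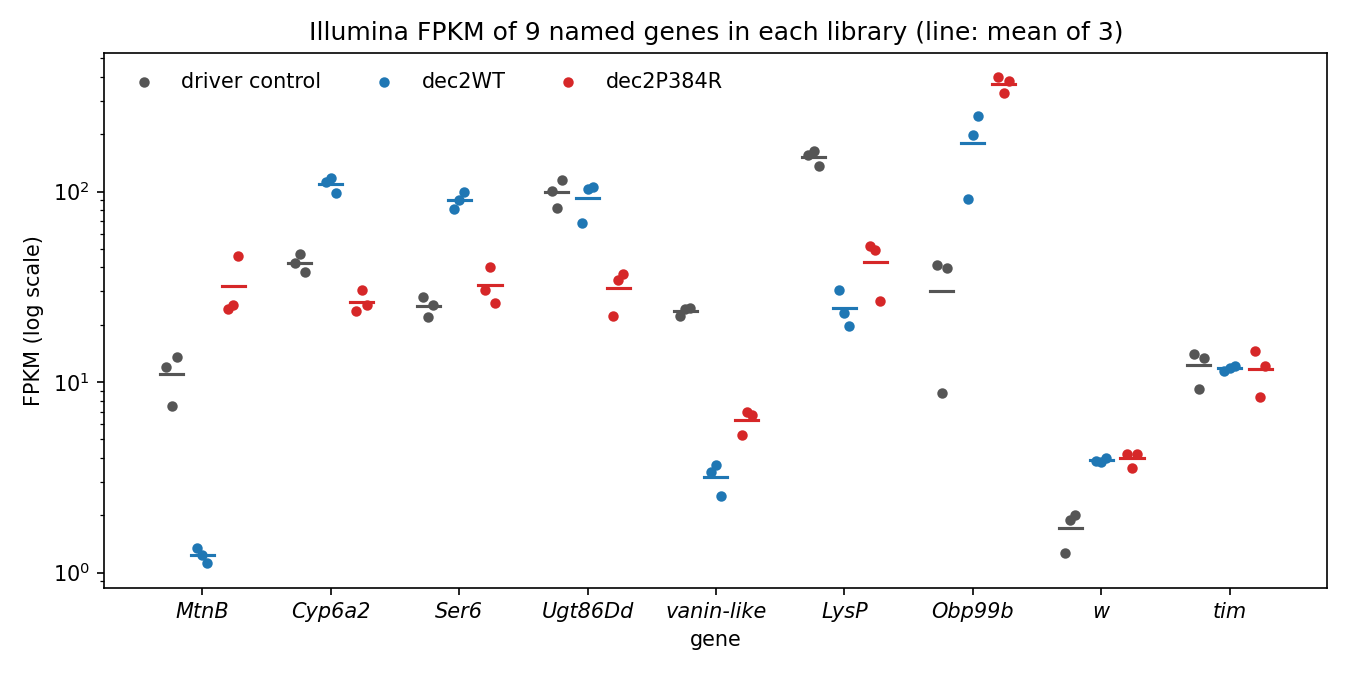
Illumina FPKM of 9 named genes on a log axis; each point is 1 library and each line the mean of the 3 libraries of a genotype. MtnB averaged 11 FPKM in the driver control, 1.24 in dec2WT and 31.9 in dec2P384R, Cyp6a2 was highest in dec2WT, and the clock gene tim lay near 12 FPKM in each genotype.

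The second comparison, dec2WT against the driver control, asked how flies with the unmutated transgene differed. MtnC rose 44.1-fold, from 2.99 ± 0.88 to 159 ± 60 FPKM (SD, n = 3 per group), with a Nanopore log2 fold change of −0.47 ± 0.26 (SE). mthl8 was at least 95-fold higher on Illumina and at least 14-fold higher on Nanopore, again against 3 control libraries without a read. Ser6, a serine protease gene, rose 3.53-fold (log2 1.82 ± 0.16 SE) and the cuticle protein gene Cpr72Ec rose 3.28-fold (1.71 ± 0.29). vanin-like fell 6.59-fold (−2.72 ± 0.14), the metallothionein gene MtnB fell 6.47-fold (−2.69 ± 0.25), LysP fell 6.19-fold (−2.63 ± 0.24) and the P450 gene Cyp6a8 fell 4.61-fold (−2.20 ± 0.18).

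Other rises under the rule were Lsp1alpha (11.6-fold), Lsp2 (6.74-fold), Obp99b (6.66-fold), Lsp1beta (5.83-fold), the Stellate family gene Ste12DOR (5.21-fold) and CecA2 (3.03-fold). Other falls were the immune peptide genes IM23 (6.31-fold) and Drsl4 (2.67-fold), the protease genes Jon66Ci (5.35-fold), Jon99Fi (4.18-fold) and gammaTry (2.70-fold), and the anaphase promoting complex gene APC7 (3.29-fold). Limma adjusted p (Benjamini-Hochberg) was 4.36e-06 for mthl8, 4.67e-06 for vanin-like, 9.97e-06 for MtnC, 0.000121 for Ser6, 0.000194 for MtnB and at most 0.0464 (Jon66Ci) for the others. Altogether 350 genes passed, 164 higher and 186 lower in dec2WT. This balance turned without driver control replicate 1 (114 higher, 89 lower) or 3 (104 and 94) and in edgeR on recovered reads (199 and 190). The count fell to 203, 195 and 198 without driver control replicate 1, 2 or 3, to 182 without dec2WT replicate 2 and to 195 without dec2WT replicate 3. Lsp1beta and Jon66Ci lost their calls in 7 of the 9 omissions of a library, Lsp2 in 5, Lsp1alpha in 4 and Obp99b and Drsl4 in 2, with limma adjusted p up to 0.19 (Jon66Ci without dec2WT replicate 2); CecA2 lost its call without dec2WT replicate 3 (0.0546). With all libraries kept, Jon66Ci also lost its call under DESeq2 (adjusted p = 0.0693), and in limma with a pseudocount of 0.1 (0.0508), with the 6 compared libraries alone (0.0716) and without a filter on low values. Calls were also lost in limma with the 6 compared libraries alone for Lsp2 (adjusted p = 0.0658), Obp99b (0.067) and Lsp1beta (0.0852), and for Lsp1beta without a filter (0.0782). Ste12DOR belongs to a family of near-identical repeats, and its value is uncertain, as are those of gammaTry, LysP and CecA2.

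Digestive serine proteases were shifted down in dec2WT too: 8 of 31 fell, 2 rose and 21 did not pass, with a median log2 fold change of −0.55 (camera adjusted p = 8.36e-08). Adjusted over the list alone, 17 proteases fell and 4 rose; Jon65Aii fell 2.08-fold and Jon65Ai 2.51-fold. The list of 51 cuticle proteins was shifted up, with a median of 0.07: TwdlD (3.75-fold), Ccp84Af (5.10-fold), Cpr49Ag (3.01-fold) and Cpr72Ec were among 5 that rose, and 46 did not pass (camera adjusted p = 0.0231); adjusted over the list alone, 8 rose and 1 fell. In the 65 accessory gland and seminal fluid protein genes, Sfp24Ba (1.99-fold), Pebp1 (1.64-fold) and Sfp93F (2.18-fold) fell and 62 did not pass, with a median of −0.10 (camera adjusted p = 0.0252); adjusted over the list alone, 3 fell and 1 rose. On Nanopore this list was shifted the other way, with a median of 0.12 (camera adjusted p = 0.0368, and 0.994 with an estimated correlation), with 1 gene, Spn77Bb, higher over all genes and over the list alone. Of 33 antimicrobial peptide genes, CecA2 and CG33470 rose, IM23 and Drsl4 fell and 29 did not pass in the main limma fit (median 0.34, camera adjusted p = 0.0315). Adjusted over the list alone, 5 rose and 2 fell. Nanopore gave the antimicrobial peptides a median of −0.36 and the opposite shift (camera adjusted p = 0.000442, and 0.994 with an estimated correlation), with 1 of 30 lower over all genes and over the list alone. Of 27 phototransduction genes, the rhodopsin gene Rh5 fell 1.40-fold and 26 did not pass (camera adjusted p = 0.00545), with 3 lower adjusted over the list alone. With an estimated correlation, adjusted p = 0.893 for the protease, peptide and phototransduction lists, 0.939 for seminal fluid proteins and 0.524 for cuticle proteins.

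Genes of energy metabolism and of the proteasome had small shifts down. In the main limma fit none had a member past the threshold over all genes or adjusted over the list alone. Median log2 fold changes were −0.17 for 89 nuclear-encoded respiratory chain genes (camera adjusted p = 0.000119), −0.13 for 25 tricarboxylic acid cycle genes (0.0109), −0.16 for 15 glycolysis genes (0.0315), −0.15 for 72 mitochondrial ribosomal protein genes (4.55e-05) and −0.10 for 37 proteasome genes (0.0231), where each value in brackets is camera's adjusted p. Testis genes (38, median 0.12, camera adjusted p = 0.0234) and starch and sugar digesting enzymes (20, median 0.47, camera adjusted p = 4.55e-05) were shifted up. In the main limma fit 0 of their members passed over all genes. Adjusted over the list alone, 2 of the sugar enzymes were higher. Adjusted p with an estimated correlation was 0.893 for these 7 lists, and 29 lists did not pass. Of these 7 lists, only the sugar enzymes passed in dec2WT on Nanopore. On Illumina, proteases, sugar enzymes, mitochondrial ribosomal proteins and phototransduction passed whichever library was left out (camera adjusted p at most 0.0369). The testis list reached 0.999 without driver control replicate 2 and the seminal fluid list 0.725 without driver control replicate 1. Rh5, Sfp93F and CG33470 each lost their calls in 5 of the 9 omissions (limma adjusted p up to 0.168, Rh5 without dec2WT replicate 2), and Pebp1 without dec2WT replicate 2 (0.0522). CG33470 also lost its call without a filter on low values (limma adjusted p = 0.0605).

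**Figure D2:**
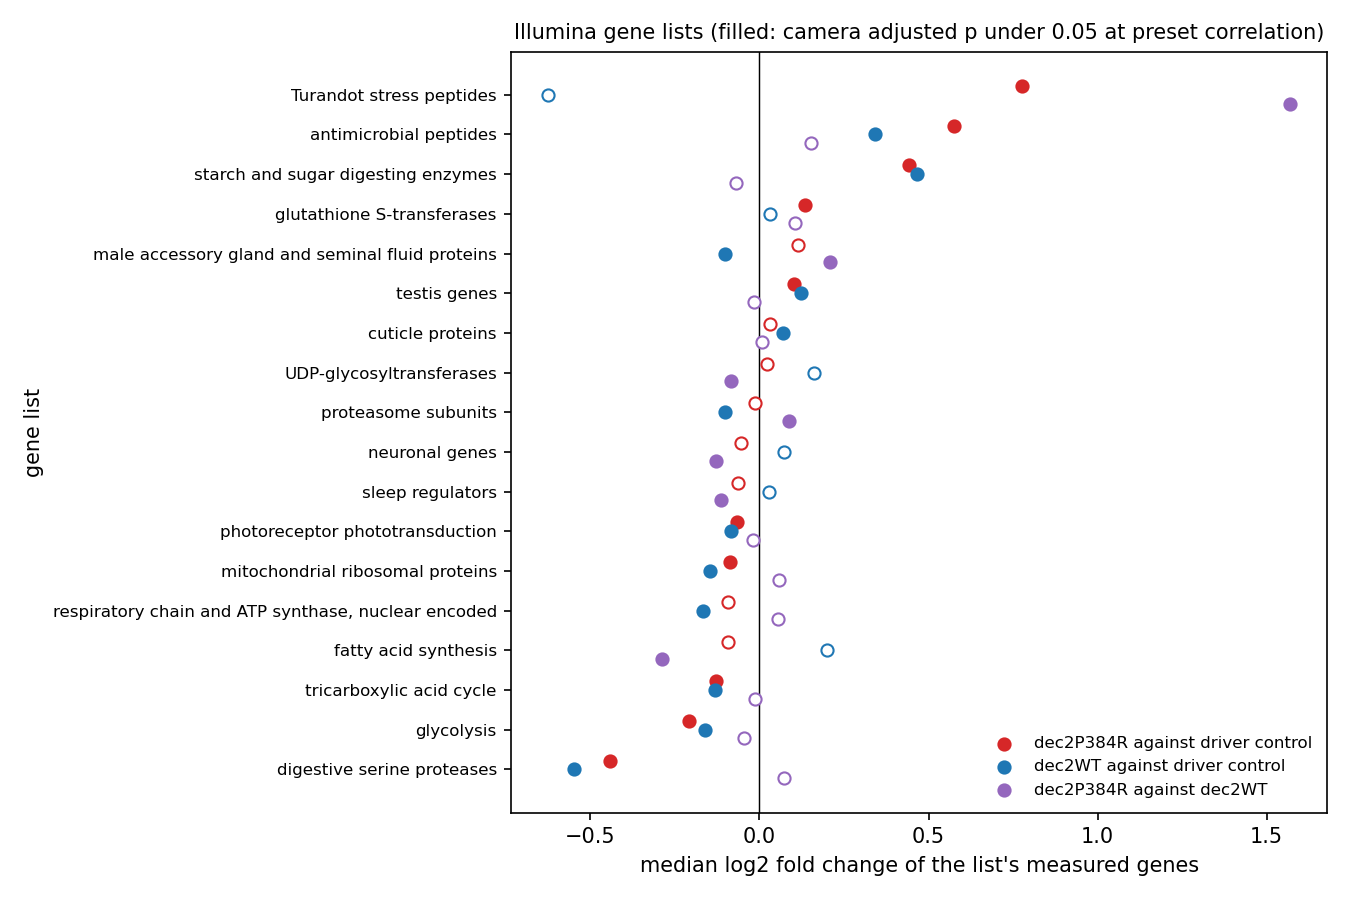
Median log2 fold change of the measured genes of each list past the camera test in at least 1 Illumina comparison, with 1 point per comparison; filled points passed at the preset correlation. Digestive serine proteases lay at −0.44 and −0.55 against the control and at 0.07 between the transgenes, and Turandot peptides at 1.57 between the transgenes.

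Many changes against the control were shared by the transgenes. Of the 376 and 350 calls, 198 were the same genes moving the same way, 102 higher and 96 lower, among them MtnC, mthl8, Obp99b, LysP, vanin-like and gammaTry. Independent lists of these sizes would share 2.68 higher and 2.18 lower genes. MtnB and Cyp6a2 were the 2 genes called in opposite directions. Across genes, which are not independent replicates, log2 fold changes correlated at r = 0.68, with a covariance of 0.085. In 100 simulated sets of unchanged groups that share 3 simulated controls, the means were 0.50 and 0.0217, a difference in covariance of 0.0633. Those sets drew every library, the controls included, around the control means, with each gene drawn on its own. They hold no deviations that many genes share, so the difference does not measure those of the real controls. The 3 control libraries cannot be split, so part of the overlap may come from their shared deviations. A genetic background that sets the control apart from both transgenic groups cannot be told apart from a transgene effect here. The shared count was 112, 98 and 97 without driver control replicate 1, 2 or 3, and 119 without dec2WT replicate 2.

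The direct comparison, dec2P384R against dec2WT, asked whether the mutant and the unmutated transgene differed. MtnB (FBgn0002869) was 17.9-fold higher in dec2P384R (log2 4.16 ± 0.25 SE), at 31.9 ± 12 against 1.24 ± 0.11 FPKM (SD, n = 3 per group); it rose in dec2P384R (1.47 ± 0.25) and fell in dec2WT (−2.69 ± 0.25) relative to the control. Cyp6a2 (FBgn0000473), a cytochrome P450 gene, was 4.10-fold lower in dec2P384R (−2.04 ± 0.13), at 26.4 ± 3.5 against 110 ± 9.7 FPKM. IM1 was 3.14-fold higher (1.65 ± 0.17). Ugt86Dd was 2.96-fold lower (−1.56 ± 0.22), Ser6 2.79-fold lower (−1.48 ± 0.16) and the muscarinic receptor gene mAChR-B 2.68-fold lower (−1.42 ± 0.15). On Nanopore the same comparison gave 3.43 ± 0.41 for MtnB, −1.83 ± 0.22 for Cyp6a2, −1.36 ± 0.19 for Ser6 and −0.37 ± 0.49 for IM1.

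Other genes higher in dec2P384R were Kmn1 (3.50-fold), the metallothionein gene MtnD (2.44-fold), Cyp6a8 (2.30-fold), Sdic4 (2.13-fold), qjt (1.97-fold), the odorant-binding protein gene Obp56h (1.94-fold), Try29F (1.91-fold) and vanin-like (1.85-fold). Lower ones were gammaTry (2.31-fold), plh (2.15-fold), the organic anion transporter gene Oatp58Db (2.09-fold), deltaTry (2.03-fold), the semaphorin gene Sema2b (2.00-fold) and Cyp310a1 (1.98-fold). Limma adjusted p (Benjamini-Hochberg) was 4.16e-05 for MtnB and Cyp6a2, 0.00113 for IM1 and mAChR-B, 0.00126 for Ser6, 0.00686 for Ugt86Dd and at most 0.0493 (Try29F) for the others. In total 105 genes passed, 67 higher and 38 lower in dec2P384R. Of these, 43 were called against the control in dec2WT alone, 35 in dec2P384R alone, 10 in both the same way, 2 in opposite ways and 15 in neither. The count was 69, 56 and 57 without dec2WT replicate 1, 2 or 3, and 65 without dec2P384R replicate 2, where 27 were higher and 38 lower. MtnB, Cyp6a2, IM1, Ser6, mAChR-B, Ugt86Dd, Obp56h and Sdic4 kept their calls whichever library was left out, and the other 12 named genes lost theirs in at least 1 omission (limma adjusted p up to 0.204, Try29F without dec2P384R replicate 2). With the 6 compared libraries alone Kmn1, MtnD, Try29F and vanin-like lost theirs, without a filter on low values Kmn1 and Try29F, and with a pseudocount of 0.1 Try29F (limma adjusted p up to 0.0943, Try29F without a filter). Sdic4 has near-identical neighbours, Cyp6a2 overlaps Epac on its own strand and Kmn1 overlaps CG11699 on the other, so these values are uncertain.

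Turandot stress peptide genes were shifted up in dec2P384R against dec2WT, with a median log2 fold change of 1.57 (camera adjusted p = 0.000137); 0 of the 4 passed over all genes and 4 were higher adjusted over the list alone. TotA stood at 462 ± 200 and 167 ± 62 FPKM (SD, n = 3 per group) and TotM at 57.3 ± 36 and 13 ± 7.6. The 65 seminal fluid protein genes were shifted up (median 0.21, camera adjusted p = 0.000155) and the 37 proteasome genes as well (median 0.09, camera adjusted p = 0.0389). Shifted down were 28 neuronal genes (median −0.13, camera adjusted p = 0.00585), 34 sleep regulators (median −0.11, 0.00585), 12 fatty acid synthesis genes (median −0.29, 0.0435) and 27 UDP-glycosyltransferases (median −0.08, 0.0318). Ugt86Dd alone passed among these over all genes, and adjusted over the list alone 3 UDP-glycosyltransferases were lower and 0 members of the other 5 lists passed. Adjusted p with an estimated correlation was 0.949 for each of the 7 lists, and 34 lists did not pass. Among these lists on Illumina, only the Turandot list passed whichever library was left out (camera adjusted p at most 0.00119). The number of lists was 12 without dec2P384R replicate 2 and 11 without dec2P384R replicate 3, and the seminal fluid list reached 0.767 without dec2P384R replicate 2. On Nanopore the sleep regulator, fatty acid synthesis, proteasome and UDP-glycosyltransferase lists did not pass. The neuronal and seminal fluid lists were shifted the other way on Nanopore, with medians of 0.26 and −0.18 (camera adjusted p = 0.0172 and 0.00495). In both, 0 members passed over all genes or adjusted over the list alone, and camera's adjusted p was 0.99 with an estimated correlation. The Turandot list did not pass there (median 0.27, camera adjusted p = 0.594, 0 of 4 past over all genes or adjusted over the list alone, adjusted p = 0.99 with an estimated correlation), with log2 fold changes of 0.28 ± 0.36 (SE) for TotA, 0.09 ± 0.42 for TotC, 0.31 ± 0.46 for TotM and 0.26 ± 0.36 for TotX.

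Clock genes did not pass in any Illumina comparison. In dec2P384R against the control, log2 fold changes were −0.25 ± 0.17 (SE, n = 3 per group) for per, −0.08 ± 0.20 for tim, −0.04 ± 0.11 for Clk, 0.16 ± 0.09 for cyc, −0.10 ± 0.19 for vri, −0.06 ± 0.17 for Pdp1 and −0.16 ± 0.16 for cry. The fly genes cwo and h, of the same bHLH-Orange family as Dec2, gave −0.04 ± 0.13 and 0.14 ± 0.10, and in dec2WT 0.06 ± 0.13 and 0.14 ± 0.10. Between the transgenes tim gave −0.05 ± 0.20 and per 0.00 ± 0.17. The list of 18 circadian genes had camera adjusted p of 0.589, 0.987 and 0.588 in the 3 comparisons, with 0 members past, also adjusted over the list alone, and adjusted p of 0.914, 0.994 and 0.949 with an estimated correlation; in dec2WT its median (0.00) and its mean (−0.01) differed in sign. On Nanopore tim had a log2 fold change of 1.61 ± 0.60 in dec2WT against the control (edgeR adjusted p = 0.349), where replicate 1 stood at 7.95 log2 CPM and the other 8 libraries at 4.89 to 5.46. There Clk had log2 fold changes of −0.59 ± 0.17 in dec2P384R and −0.70 ± 0.16 in dec2WT (edgeR adjusted p = 0.202 and 0.0855), against −0.04 ± 0.11 and 0.18 ± 0.11 on Illumina. It stood at 5.35 to 5.54 log2 CPM in the 3 control libraries and 4.41 to 4.96 in the other 6. The value of 4.41 was that of dec2WT replicate 1, the library with high tim, and dec2WT replicates 2 and 3 stood at 4.93 and 4.85. Clk overlaps CG32371 on its own strand, so its value is uncertain. The eye colour gene w, a common marker of fly transgenes, rose 2.04-fold in dec2P384R (1.03 ± 0.15, limma adjusted p = 0.0035) and 2.01-fold in dec2WT (1.01 ± 0.15, limma adjusted p = 0.00372), and between the transgenes its log2 difference was 0.02 ± 0.15; w overlaps kirre, so its value is uncertain.

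**Figure D3:**
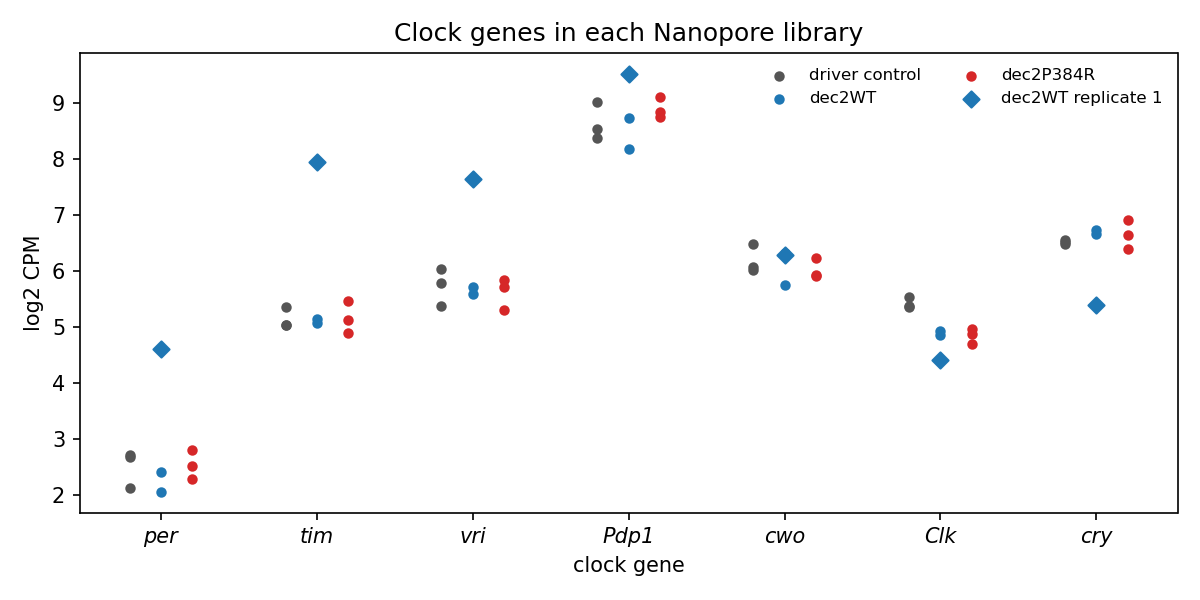
Log2 CPM of 7 clock genes in the 9 Nanopore libraries, with 1 point per library, genotypes in colour and dec2WT replicate 1 as a diamond. That library lies above the others for per (4.61), tim (7.95), vri (7.64) and Pdp1 (9.52) and below them for Clk (4.41) and cry (5.40).

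On Nanopore, which had fewer reads, 54 genes passed in dec2P384R against the control (25 higher, 29 lower), 91 in dec2WT against the control (33 higher, 58 lower) and 15 between the transgenes (8 higher, 7 lower in dec2P384R). gammaTry, deltaTry, LysP, mthl8 and Ugt86Dd passed in dec2P384R, with edgeR adjusted p of 2.69e-05, 0.00395, 0.00349, 0.000396 and 0.031. vanin-like, MtnB, Ser6, Cyp6a8, LysP, gammaTry and mthl8 passed in dec2WT, with edgeR adjusted p of at most 0.00823 (vanin-like). Between the transgenes MtnB, Cyp6a2 (both 0.00384), Ser6 (0.00765) and Oatp58Db (0.0215) passed. The balance turned in dec2P384R without dec2P384R replicate 2 (15 higher, 12 lower) or 3 (42 and 28), and in dec2WT it was 33 and 34 without dec2WT replicate 1. The first count was 35 without driver control replicate 1 or 2 or dec2P384R replicate 1, and 27 without dec2P384R replicate 2. The second was 49, 60 and 53 without driver control replicate 1, 2 or 3, 57 without dec2WT replicate 3, and 67 without dec2WT replicate 1, the library with high tim.

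Nanopore list tests passed for 8 lists in dec2P384R, 11 in dec2WT and 5 between the transgenes at the preset correlation, and for 0 with an estimated one. Starch and sugar digesting enzymes were shifted up in both transgenic groups here too (medians 0.43 and 0.43, camera adjusted p = 0.0025 and 0.000715). Of 19 measured, 0 passed over all genes or adjusted over the list alone, and adjusted p was 0.983 and 0.994 with an estimated correlation. This list lost its call in 3 of the 9 omissions of a library in dec2P384R and in 1 in dec2WT. Its camera adjusted p reached 0.159 and 0.0719, both without driver control replicate 1. Digestive serine proteases were shifted down in dec2WT, with 3 of 30 lower and 1 higher (camera adjusted p = 0.000274), 11 lower and 2 higher adjusted over the list alone, and adjusted p = 0.4 with an estimated correlation. In dec2P384R the protease list gave a camera adjusted p of 0.249. Turandot peptides were shifted up in dec2P384R (median 0.88, camera adjusted p = 0.0169; 0 of 4 past over all genes, 2 higher adjusted over the list alone). Shifted down in dec2P384R were 13 mitochondrially encoded genes (median −0.47, camera adjusted p = 0.00124) and 33 genes of insulin, TOR and FOXO signalling (median −0.32, 0.0025), with 0 members past over all genes; adjusted over the list alone, 2 and 0 were lower. With an estimated correlation, adjusted p = 0.983 for these 3 lists in dec2P384R. The mitochondrially encoded list and the insulin, TOR and FOXO list also passed in dec2WT (camera adjusted p = 0.0269 and 0.0153). There each lost its call in 2 of the 9 omissions of a library. The number of lists in dec2P384R was 5 without driver control replicate 1 and 2 without dec2P384R replicate 2, and in dec2WT it was 7 without driver control replicate 1 or dec2WT replicate 1. Between the transgenes it was 0, 3 and 11 without dec2WT replicate 1, 2 or 3, and 8 and 3 without dec2P384R replicate 1 or 2.

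Illumina calls kept their direction on Nanopore for the most part. Of the calls measured on both platforms, 207 of 233 (88.8%, exact binomial 95% interval 84.1 to 92.6) had the same sign in dec2P384R against the control. The same held for 201 of 217 (92.6%, 88.3 to 95.7) in dec2WT and for 61 of 66 (92.4%, lower limit 83.2) between the transgenes. Genes are not independent replicates, so the intervals cover counting error alone; over all 10800 genes measured on both platforms the shares were 58.7%, 58.6% and 54.4%. Genes past the threshold on both in the same direction numbered 37, 55 and 11, including mthl8, gammaTry, LysP, Ser6, MtnB and Cyp6a2. Exceptions among the largest rises in dec2P384R were MtnC (Nanopore log2 fold change −0.16 ± 0.26) and IM1 (−0.20 ± 0.49).

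**Figure D4:**
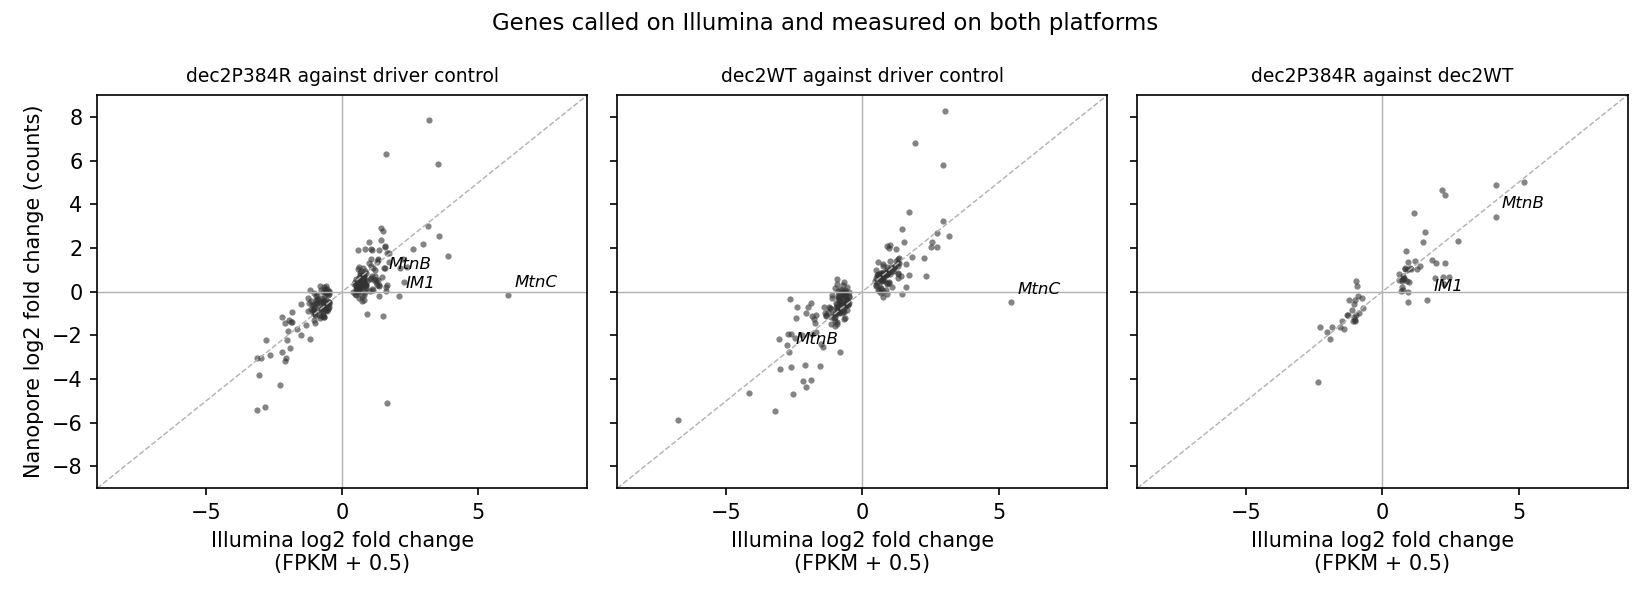
Log2 fold changes of genes called on Illumina, with Illumina (FPKM + 0.5) on the horizontal axis and Nanopore (counts) on the vertical; each point is 1 gene and the dashed line marks equal values. MtnB follows the line between the transgenes (4.16 and 3.43), whereas MtnC lies near 0 on Nanopore in both comparisons with the control.

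The authors' deposited table for Illumina lists 244 calls of at least 2-fold in dec2P384R against the control, 286 in dec2WT and 93 between the transgenes. Of the limma calls of at least 2-fold, 174 of 198, 177 of 189 and 64 of 71 are in the authors' deposited table with the same direction. For Nanopore the authors' deposited table has 114, 135 and 35 genes with adjusted p under 0.05, and it holds 49 of the 54, 76 of the 91 and 13 of the 15 edgeR calls with the same direction.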

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

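The differences between platforms follow a rule fixed before the data were examined, whereas the tests of all 3 patterns weighed here were chosen after the results were seen.

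Log2 fold changes of these named genes differed between the platforms in a test of the difference itself, given as Illumina less Nanopore. In dec2P384R against the driver control the differences were 6.23 for MtnC, 2.30 for IM1, 1.36 for CecA2, 1.06 for Mst57Da, 0.73 for h, 0.55 for Clk, −0.62 for mRpS10, −0.67 for deltaTry and −0.88 for vanin-like. In dec2WT against the control they were 5.93 for MtnC, 3.44 for AttA, 1.40 for CecA2, 1.09 for gammaTry, 0.87 for Clk, 0.74 for h, −0.96 for Sfp93F, −1.15 for Sfp24Ba and −2.32 for IM23. Between the transgenes they were 2.02 for IM1, 1.45 for Obp56h, 0.88 for Sfp23F and −1.32 for CG5999.

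MtnC rose 67.5-fold and 44.1-fold on Illumina but stood at 364, 262 and 326 CPM on Nanopore in the control, dec2WT and dec2P384R. Too few Nanopore reads are argued against by the counts of MtnC, of which the lowest in a library was 491. Metal exposure is argued against in dec2WT by MtnB alone, whose log2 fold change was −2.69 ± 0.25 (SE) on Illumina and −2.77 ± 0.42 on Nanopore. MtnA (0.58 ± 0.20 on Illumina) and MtnD (0.06 ± 0.22) do not decide it. The largest upper 95% limit of these genes was 0.97 by a normal approximation, which allows a rise of nearly 2-fold. Metal exposure stays open in dec2P384R, where MtnB and MtnD rose on Illumina (largest limit 1.96). On Nanopore none of MtnA, MtnB and MtnD passed in dec2P384R (edgeR adjusted p at least 0.463). Their log2 fold changes there were −0.25 ± 0.34 (SE) for MtnA, 0.65 ± 0.31 for MtnB and 0.30 ± 0.21 for MtnD. A loss of Illumina reads in the control alone, for example through a sequence variant that keeps short reads from aligning, stays open: the ratio of FPKM to CPM lay at percentile 5.61 of 107 genes of like length and level in the control, against 40.2 and 40.9 in dec2WT and dec2P384R. That position is low but not outside the other genes, so the rise of MtnC may be technical, and it cannot be told apart from a real one here.

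In the Nanopore library of dec2WT replicate 1, the mean log2 CPM of per, tim, vri and Pdp1 less that of Clk and cry was 2.53, against −0.58 to −0.03 in the other 8 libraries. Collection at another time of day is consistent with this value, because these sets of genes peak at different hours, although cwo (6.29) lay within the range of the others. An exchange with a library of another genotype is argued against, since over 217 and 66 called genes the library lay 100% and 107% of the way from the control and from dec2P384R to the other dec2WT libraries. An effect of the dec2WT transgene is argued against by Illumina, where the upper 95% limit of the log2 fold change of tim was 0.35.

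Calls between the transgenes crowded on the X chromosome on Illumina: 34 of 105 (32.4%) against 15.2% of tested genes (Fisher exact p = 8.17e-06), while dec2P384R and dec2WT against the control had 14.1% and 16.6%. On Nanopore 9 of the 15 calls between the transgenes lay on the X, a share that was not tested. Another dosage compensation of the whole X is argued against by a median log2 fold change of X genes that lay −0.0064 from that of chromosomes 2 and 3, and another mix of the sexes by the female markers Yp1, Yp2, osk and Vm26Ab, at most 2.29 FPKM in the 6 transgenic libraries. With 1 call kept per 100 kb window, 21 of 76 were on the X (Fisher exact p = 0.00547, against all genes not called). Repeated calls from clusters of neighbouring genes are thus argued against as the only source of the crowding. Shared reads stay open for the 1 call kept in a window and for families spread more widely. Fisher's test also treats linked genes as independent. An X chromosome of other origin in dec2WT stays open: the share was 21.3% of calls in dec2WT alone and 15.3% in dec2P384R alone (Fisher exact p = 0.194). The labels name 1 genotype per transgene. For these genes and all others, an effect of the mutation therefore cannot be told apart from one of genetic background. The same holds for effects of a transgene against the driver control.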

How the results depend on the processing

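The tests of recovered reads with edgeR, the pseudocounts, the TMM rescaling and the omission of Nanopore dec2WT replicate 1 from the platform comparison were chosen after the data were seen, and the other alternatives before. Median-of-ratios scaling in place of TMM, planned for both platforms, is the deposited scale of Illumina and was run there as TMM rescaling.

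Counts of genes stayed within 1.5 times their value under most alternatives. For dec2P384R against the driver control on Illumina (376), with all 3 libraries of each compared genotype kept, they ran from 287 with the 6 compared libraries alone to 562 with DESeq2. DESeq2 moved 3 other counts further: 186 between the transgenes on Illumina, and on Nanopore 103 for dec2P384R against the control and 41 between the transgenes; the cause was not tested. With replicate number as a block the counts were 504, 473 and 130 on Illumina (dec2P384R against control, dec2WT against control, between transgenes) and 39, 68 and 12 on Nanopore. With it Jon66Ci in dec2WT and Try29F between the transgenes were not called on Illumina (limma adjusted p = 0.0637 and 0.0678). The block gave 9, 14 and 8 lists on Illumina and 8, 12 and 5 on Nanopore, 261 genes shared by the transgenes, and 87.5%, 92.1% and 88.5% of calls with the same direction on both platforms.

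In each of the 6 list results 0 lists passed with an estimated correlation, which was 0.01 in the preset and is taken from the data in this setting. Without a filter on low values, 7 lists passed for dec2WT against the control on Nanopore; the cause was not tested.

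Leaving out 1 library in turn, where a remaining pair is assumed to vary like the other groups, gave these ranges. Genes on Illumina: 179 to 354 for dec2P384R against the control, 182 to 387 for dec2WT and 56 to 103 between the transgenes. Genes on Nanopore: 27 to 70, 49 to 96 and 10 to 17. Lists on Illumina: 4 to 14, 11 to 14 and 5 to 12; on Nanopore: 2 to 10, 7 to 12 and 0 to 11. The genes shared by the transgenes ran from 97 to 195, and the same direction on both platforms from 86.9% to 93.8%, 89.6% to 94.7% and 85.4% to 94.7%. In dec2P384R on Illumina, camera's adjusted p ran from 3.69e-09 to 0.974 for mitochondrial ribosomal proteins, whose direction reversed without dec2P384R replicate 3, and from 3.69e-05 to 0.967 for testis genes, which reversed without driver control replicate 2. Without Nanopore dec2WT replicate 1 alone, the same direction was 89.2%, 94.1% and 94.4%. Fewer libraries give the tests less power by construction.

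Over all alternatives, results of single named genes were the same in 3076 cases, lost their call in 168, gained one in 51 and reversed in 0. Genes called in neither fit count as the same here. DESeq2 on recovered reads gave 16 of the gains and the replicate block 10. Among the named genes called, some lost their call in at least 1 omission. They were 9 of 27 in dec2P384R against the control, 11 of 31 in dec2WT and 12 of 20 between the transgenes. Results of lists were the same in 521, lost in 166 and reversed in 2. In simulated data for dec2P384R against the control, 74.6% of genes changed 2-fold were recovered on Nanopore and 98.5% on Illumina, which differ in test and filter as well as in depth.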

Other observations

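The values of single genes in the next 2 paragraphs, the sex markers among them, were singled out after they were seen, whereas the other splits of the libraries were planned, except the regroupings within replicate numbers, which were added after the results were seen.

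CG34026 fell in dec2WT, from 94.1 to 0.648 FPKM on average (log2 −6.78 ± 0.68 SE, n = 3 per group, limma adjusted p = 0.000298), and stood at 38.3 FPKM in dec2P384R, with a Nanopore log2 fold change of −5.90 ± 0.65 in dec2WT (edgeR adjusted p = 0.000684). msl-3, of the X dosage compensation complex, rose in dec2WT (1.00 ± 0.11, limma adjusted p = 0.000541; Nanopore 1.99 ± 0.38, edgeR adjusted p = 0.0312) and had a log2 fold change of 0.04 ± 0.11 in dec2P384R (Nanopore 0.90 ± 0.41, edgeR adjusted p = 0.446). CG45154 (X, 21146281 to 21147041) had no Illumina reads in dec2WT and was at least 38-fold higher in the control and at least 37.4-fold higher in dec2P384R. jb, also on the X, had none in dec2WT and was at least 8.89-fold higher in the control. In all, 10 genes had no reads in 1 genotype and at least 20 in each library of another.

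Some Nanopore calls had no Illumina counterpart. Unc-115b had log2 fold changes of 5.37 ± 0.30 in dec2P384R and 5.41 ± 0.29 in dec2WT on Nanopore (edgeR adjusted p = 2.35e-06 and 1.75e-06), and 0.29 ± 0.17 and 0.56 ± 0.17 on Illumina. isoQC had 1.84 ± 0.17 and 2.40 ± 0.17 on Nanopore (edgeR adjusted p = 0.000184 and 1.29e-05), and −0.06 ± 0.10 and −0.04 ± 0.10 on Illumina. Sex markers had a male profile in the 9 Illumina libraries: Yp1 at 0.238 to 1.69 FPKM and osk at 0 to 0.126, against Mst87F at 381 to 556 and Acp36DE at 212 to 409.

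Every way of dividing the 6 libraries of a comparison into 3 and 3 was tested; these are 10 splits, too few for a share under 0.05. On Illumina the real split gave 376, 350 and 105 genes (dec2P384R against control, dec2WT against control, between transgenes) and the highest other split 2, 1 and 0, so that 1 of 10 splits, the real one, gave as many in each. Calls with the same direction on both platforms numbered 207, 201 and 61, and 1, 1 and 0 in the highest other split, again with 1 of 10 as large. This number cannot exceed the calls of a split, of which the others had at most 2, 1 and 0. It therefore repeats the count of calls and does not test the agreement of the platforms. On Nanopore the real split gave 54 and 91 genes against the control and the highest other 0 and 2 (1 of 10 as large in each). Between the transgenes on Nanopore it gave 15 and another 17 (2 of 10 as large), the one that joins dec2WT replicate 1 with dec2P384R replicates 1 and 3. For dec2P384R against the control on Illumina, the numbers were taken to pair the libraries. The other 3 splits that part every pair gave 0 genes by limma without a block.

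Gene lists came out otherwise. On Illumina the real split gave 10, 12 and 7 lists and the highest other 16, 15 and 19, with 9, 3 and 10 of the 10 splits as large. On Nanopore the real split gave 8, 11 and 5 lists and the highest other 13, 18 and 13, with 5, 4 and 8 of 10 as large. Splits that mix the genotypes gave as many lists as the real split or more in each comparison, with 19 against 7 between the transgenes on Illumina. Whether this comes from a structure of the samples apart from genotype or from a preset correlation that is too low was not tested; with an estimated one 0 lists passed in the real split. For the 198 genes shared by the transgenes, 100 regroupings of the 9 libraries were counted, the real one included. The highest other gave 151, and 1 of 100 was as large. Of 100 regroupings that exchange libraries within a replicate number, again 1 was as large and the highest other gave 139. Both of these highest others kept the 3 control libraries together and mixed the transgenic ones. Those that broke up the controls gave at most 24 and 50. Only 2 and 3 of the drawn regroupings kept the controls together, with 139 to 151 and 128 to 139 genes. The draws argue against a random division of the 9 libraries, but they cannot exclude a deviation or background shared by the 3 controls.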
